A study of Rattus norvegicus with 12 samples.

How the data were processed

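The series holds 12 Agilent whole rat genome arrays, hybridized each with Cy3-labelled RNA of 1 cribriform mammary tumour. Per the labels, the rats were female Sprague-Dawley rats with an age of 11 weeks and 8 weeks of treatment (the time point of that age is not given in the sources used here), and 3 tumours stand for each of 4 groups. Per the series design text, all rats received 1 injection of MNU, the tumours of a group came from different rats, and the groups received corn oil, corn oil and tamoxifen, fish oil, or fish oil and tamoxifen. Doses are not given in the sources used here. Per the labels' protocols, total RNA was labelled with a one-colour kit.

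The deposited intensity values of each array are scanner output of Agilent Feature Extraction 9.5.3.1, per the file headers. The processed signal was detrended within the array, with substitute values for dim spots, and was not normalized between arrays, per the file headers. The mean spot signal and the median local background are deposited intensities with no correction. The authors deposited also a series matrix of log2 values for 11078 probes. All its columns hold the same sorted values, as quantile normalization gives, and how its probes were chosen is not given in the sources used here. Per the file headers, the 12 arrays lay on 3 slides of 4, and each slide held 1 array of every group with the same replicate number.

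From these files, control spots (1639 of each array) were left out and the spots of one probe averaged, which left 41012 probes. Spots with an outlier flag were set to missing, and 122 probes were left out for this. The log2 of the processed signal minus the array's 75th percentile was analysed. A probe was tested when it was well above background, by the scanner's flag, on all 3 arrays of at least 1 group (19506 probes). Probes were named with the reference list of genes by accession (10735), symbol (5571) or synonym (3729), 3371 kept the name in the file, and 17606 had no gene name. The brightest probe stood for each of the 2432 genes with several probes. This gave 16556 features, of which 10767 had a gene name.

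One linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8) for reading. Moderated t tests had 8 residual and 3.73 prior degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 8 comparisons were tamoxifen under each diet, fish oil with and without tamoxifen, both together against corn oil, the interaction, and the averages of the tamoxifen and of the fish oil effects. The 26 gene lists had 764 members, of which 708 were on the array and 539 were tested. Tumours with one number shared a slide. In the tamoxifen comparisons within a diet, all 6 pairs on one slide had deviations from their group means correlated over 0.1 (0.17 to 0.428). Of the 12 other pairs of a slide 4 did, and pairs from different slides reached 0.413. The pairing thus went with diet and slide together, and slide alone does not mark it. The main fit had no block, and the only block fitted as an alternative was slide. The lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The fit and camera were tested on simulated data of the same size, where 100 genes per fold were changed in 5 simulations and the share of false calls was 4% to 5.3%. Camera called the shifted list in all 5. The simulated genes varied independently and no slide effect was simulated. The false calls and camera were therefore not tested under correlation between genes or arrays.

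Named genes were chosen by a fixed rule. Among genes with a symbol past the threshold, up to 10 with the largest change were named in each direction for the simple effects, where the groups also had to separate, and up to 6 for the other comparisons. Where none passed, 5 with the smallest p in each direction were named as values. To these came up to 4 members of each list with the smallest p and the genes Esr1, Pgr, Csn2, Mki67 and Cd8a. For the fold bounds ("at least"), each array of a dim group was set to the lowest signal called well above background on it, or to the gene's own signal where that was higher. In the averages and the interaction a bound is given only where every dim group was on the lower side. A dim group has no array well above background. Dim arrays of other groups kept their own signal, so a fold is not a lower bound where they lie on the lower side.

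The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter, a filter on all 12 arrays, the mean of a gene's probes, eBayes with trend and robust options, array weights, replicate number and slide as a block, the series matrix values, a fit of the compared groups only, and leaving out each array. Normexp without spots with a background outlier was added after its fitted background mean came out at -304 on corn oil 2, -383 on corn oil 3 and -575 on fish oil + tamoxifen 3, against 0.696 to 7.64 on the other arrays. Unnamed probes were tested but are not described, and a few genes chosen by the naming rule are not described here. Probe positions are those of the rn3 build in the files, and no genome sequence was used.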

Results

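The series measured gene expression in mammary tumours of female Sprague-Dawley rats that had received MNU (N-methyl-N-nitrosourea), a carcinogen that induces mammary tumours. Rats were fed a diet with corn oil, rich in n-6 fatty acids, or with fish oil, rich in n-3 fatty acids. Each diet was given with or without tamoxifen, a drug that binds the estrogen receptor and blocks it in mammary tissue. Tumours of the cribriform type were taken after 8 weeks of treatment. Each of the 4 groups (corn oil, corn oil + tamoxifen, fish oil, fish oil + tamoxifen) was represented by 3 tumours from 3 different rats, 1 array each. The p-values of single genes thus measure spread between animals. The arrays lay on 3 slides, and each slide held 1 array of every group. Arrays are named below by group and replicate number, which is also the slide number. The 75th percentile of the processed signal ran from 428.5 to 753.9 intensity units, 44.5% to 52.0% of the probes were well above background, and no spot was saturated. Across genes, Pearson's r ran from 0.940 to 0.976 between arrays of one group and from 0.925 to 0.976 between arrays of different groups. Corn oil 2 had the lowest mean r with the other arrays, 0.947. With 3 arrays per group, the number of arrays limited the precision of every value.

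A total of 16556 genes or unnamed probes were tested with limma. The 26 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 between genes. The list p-values at that setting rest on the assumed correlation and do not measure spread between animals. None of the 83 list calls reported below held when camera estimated that correlation, so each is given with both values. Gene changes are log2 differences with standard errors, n = 3 per group. A fold given as "at least" is a bound for the processed signal alone. The rule gave 23 such folds, those of Kynu and Scin below included. Of these, 22 were not reached under normexp background correction, 11 of 19 under normexp without background-outlier spots and 9 of 20 in the series matrix values. The background mean fitted by plain normexp was strongly negative on corn oil 2 (-304), corn oil 3 (-383) and fish oil + tamoxifen 3 (-575). Values given below as under normexp are from that fit.

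Averaged over both diets, tamoxifen changed 78 genes or unnamed probes, 62 higher and 16 lower, and 40 of the 78 had a gene name. In 66 of the 78, all 6 tamoxifen tumours lay on one side of the 6 others. Igf2, an insulin-like growth factor, fell by 3.89 ± 0.72 on the log2 scale, a 14.8-fold difference (adjusted p = 0.0447). Its level in corn oil 2 was within the range of the tamoxifen tumours. Npw, which encodes neuropeptide W, fell by 1.44 ± 0.23 (adjusted p = 0.0295) and Chl1, a cell adhesion molecule, fell by 1.43 ± 0.27 (adjusted p = 0.0495). B4galnt4, a glycosyltransferase, fell by 1.24 ± 0.23 (adjusted p = 0.0447) and Epb41l4a, a membrane-cytoskeleton protein, fell by 1.02 ± 0.19 (adjusted p = 0.0476). Among the higher genes, Sh2d1a, an adaptor of T and NK cell signalling, rose 4.59-fold (2.20 ± 0.34, adjusted p = 0.0274). Kynu, an enzyme of tryptophan breakdown, was 3.79-fold higher (adjusted p = 0.0305) and Scin, an actin-severing protein, 4.01-fold (adjusted p = 0.0351), with only the fish oil group raised as for the bounds. For both, 1 array of the corn oil group and none of the fish oil group was well above background. The dim corn oil arrays kept their own signal, so these folds are not lower bounds. Slc27a2, an acyl-CoA synthetase and fatty acid transporter (at least 1.89-fold higher, adjusted p = 0.0274), and Gpr141, an orphan receptor (at least 1.47-fold higher, adjusted p = 0.0274), were not well above background on any array without tamoxifen. Dgkb, a diacylglycerol kinase (at least 4.09-fold higher, adjusted p = 0.0274), was not on any array of the corn oil group. Under normexp the log2 changes were 0.65 for Kynu, 0.90 for Scin, 0.66 for Slc27a2, 0.51 for Gpr141 and 0.99 for Dgkb, all below the log2 of the folds given for them. Cesl1, a carboxylesterase-like gene, was lower (adjusted p = 0.0356) and was well above background in the fish oil group alone, so no size is given. Within each of the 3 slides, all 12 genes had the sign of the whole. The genes were chosen for their change on these same arrays, so neither these signs nor the separation of the tumours is independent support. The slide values of Igf2 were -4.09, -3.03 and -4.55 and those of Sh2d1a 2.72, 2.84 and 1.04. The probe of Igf2 lies on chromosome 1 at 203094707 to 203094766 and that of Sh2d1a on chromosome X at 2539718 to 2539777, in the rn3 build.

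**Figure D1:**
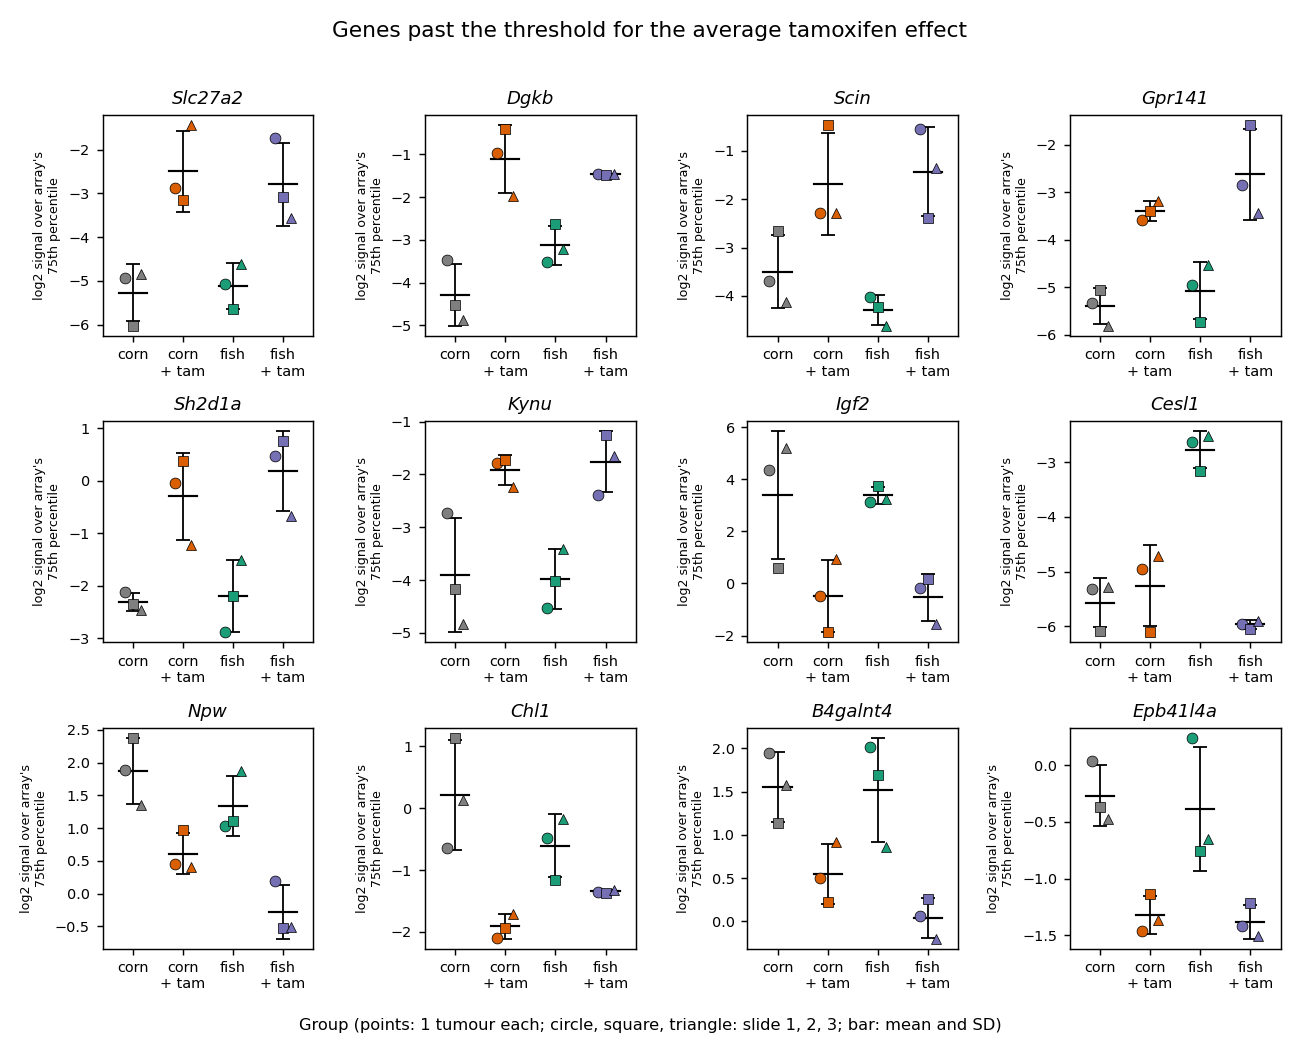
Log2 signal minus the 75th percentile of the array for the 12 named genes past the threshold for the average tamoxifen effect. The genes were chosen from these same arrays. Points are single tumours, with the slide given by the symbol, and bars are the group mean and SD (n = 3); in 9 of the 12 genes, all but Igf2, Cesl1 and B4galnt4, the 6 tamoxifen tumours lie on one side of the 6 others.

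Markers of immune cells were higher with tamoxifen and genes of milk secretion lower. The T and NK cell list had 19 of 20 members positive, with a median of 1.18 (adjusted p = 7.61e-09, and adjusted p = 0.418 with an estimated correlation). Its median within slides was 1.63, 1.99 and 0.04. Over all genes 2 members passed, Sh2d1a and the chemokine Ccl5 (1.94 ± 0.36, adjusted p = 0.0457), and 14 passed adjusted over the list alone. The mast cell list had 12 of 13 members positive, a median of 1.21 and slide medians of 0.95, 0.94 and 1.98 (adjusted p = 5.63e-06, and adjusted p = 0.418 with an estimated correlation). The mast cell protease Cpa3 (2.09 ± 0.37, adjusted p = 0.0401) passed over all genes and 6 members adjusted over the list alone. The macrophage and dendritic cell list had 22 of 24 positive, a median of 0.53 and slide medians of 0.67, 0.77 and -0.02 (adjusted p = 2.62e-05, and adjusted p = 0.505 with an estimated correlation). In it 3 members passed adjusted over the list alone, among them the mannose receptor Mrc1 (0.89 ± 0.19). All 6 tested members of the B and plasma cell list were positive, with a median of 0.98 and slide medians of 0.67, 1.49 and 0.36 (adjusted p = 0.000688, and adjusted p = 0.168 with an estimated correlation). Of these, 4 passed adjusted over the list alone. Of the milk and secretory differentiation list, 16 of 19 were negative, with a median of -0.89 and slide medians of -0.68, -0.42 and -0.97 (adjusted p = 4.36e-06, and adjusted p = 0.168 with an estimated correlation). Aldoc, a glycolytic aldolase on that list, fell by 0.90 ± 0.16 (adjusted p = 0.0345). Adjusted over the list alone 6 members passed, among them Olah, which ends medium-chain fatty acids in milk (-1.68 ± 0.33).

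None of the 4 marker genes named in every comparison passed for tamoxifen. The casein gene Csn2 had -1.91 ± 0.95 (adjusted p = 0.302), with -1.22 without corn oil 3 and -1.24 without fish oil 1, and Cd8a of cytotoxic T cells 1.25 ± 0.55 (adjusted p = 0.252). The proliferation marker Mki67 had 0.16 ± 0.21 (adjusted p = 0.734), and 0.04 to 0.31 leaving out an array. The progesterone receptor gene Pgr had -0.00 ± 0.39 (adjusted p = 0.998) and was positive under median centring and array weights, with -0.32 to 0.26 leaving out an array. The estrogen receptor gene Esr1 was not well above background on any of the 12 arrays and was not tested.

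Averaged over the diets, fat, vessel and luminal markers were lower with tamoxifen, but fat and vessel markers were not lower under corn oil. The adipocyte list had 14 of 16 negative (median -0.83, adjusted p = 0.000688, and adjusted p = 0.505 with an estimated correlation), with medians of -1.91 under fish oil and 0.57 under corn oil (11 of 16 positive, adjusted p = 0.411). The endothelial list had 16 of 19 negative (median -0.52, adjusted p = 0.000688, and adjusted p = 0.505 with an estimated correlation), with medians of -0.98 under fish oil and 0.04 under corn oil (11 of 19 positive, adjusted p = 0.928), and the luminal epithelial list 21 of 24 (median -0.20, adjusted p = 0.00141, and adjusted p = 0.31 with an estimated correlation). The interferon response list was higher (32 of 40 positive, median 0.33, adjusted p = 0.00843, and adjusted p = 0.72 with an estimated correlation), with the chemokine gene Cxcl10 (1.45 ± 0.31) among those past the threshold adjusted over the list alone. Its median was 0.72 under corn oil and -0.07 under fish oil (16 of 40 positive, adjusted p = 0.948). Cytokines, chemokines and eicosanoid synthesis were higher (14 of 20, median 0.39, adjusted p = 0.0323, and adjusted p = 0.497 with an estimated correlation), as was antigen presentation (15 of 20, median 0.20, adjusted p = 0.0323, and adjusted p = 0.611 with an estimated correlation). In each of the cytokine and antigen presentation lists, 2 members passed adjusted over the list alone. Immediate early and heat shock genes were lower (18 of 24 negative, median -0.29, adjusted p = 0.0252, and adjusted p = 0.617 with an estimated correlation). The other 14 lists had adjusted p from 0.101 (erythroid) to 0.946, among them estrogen-responsive genes (12 of 24 positive, median 0.02). Neutrophil genes had a median of 0.22 (2 of 3 positive), skeletal muscle 0.32 (7 of 10), fatty acid synthesis 0.06 (11 of 21) and apoptosis 0.01 (13 of 25). Medians were -0.02 for myoepithelial and basal (8 of 17), -0.11 for oxidative stress response (9 of 24) and -0.24 for squamous epithelium genes (1 of 4). Proliferation had 25 of 47 positive and a median of 0.06, while its test leaned to the lower side (adjusted p = 0.578). The call for antigen presentation was lost without corn oil 1 (median 0.17), corn oil 3 (0.12), corn oil + tamoxifen 2 (0.15), fish oil 1 (0.18), fish oil + tamoxifen 1 (0.16) and fish oil + tamoxifen 2 (0.10). The call for interferon genes was lost without corn oil 1 (median 0.22), corn oil 3 (0.22), corn oil + tamoxifen 3 (0.21), fish oil 3 (0.27) and fish oil + tamoxifen 1 (0.20). The call for cytokine genes was lost without corn oil 1 (median 0.33), corn oil + tamoxifen 2 (0.35), corn oil + tamoxifen 3 (0.35), fish oil 2 (0.34), fish oil + tamoxifen 1 (0.30) and fish oil + tamoxifen 2 (0.30). The call for immediate early genes was lost without corn oil 2 (median -0.08), corn oil + tamoxifen 2 (-0.20), fish oil 1 (-0.20) and fish oil + tamoxifen 3 (-0.23). Medians moved by over 1.5 times, with the call kept, for antigen presentation (0.32 without fish oil + tamoxifen 3) and interferon genes (0.17 without fish oil 1 and 0.51 without fish oil 2). Others were immediate early genes (-0.47 without corn oil 1).

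The count of 78 was sensitive to single arrays. No gene passed without corn oil 3, corn oil + tamoxifen 1, fish oil 1 or fish oil + tamoxifen 1. Without fish oil 2, 4 passed, 7 without fish oil + tamoxifen 2, 20 without fish oil 3, 42 without corn oil 1 and 143 without fish oil + tamoxifen 3. Dgkb lost its call in 4 of the 12 fits with an array left out, Sh2d1a in 6, Npw in 8, Igf2 in 10 and Epb41l4a in 12. With slide as a block 72 genes passed, 52 of the 78 among them, while Kynu, Igf2, Chl1, B4galnt4 and Epb41l4a had adjusted p from 0.0533 to 0.0631. Of simulated changes in this comparison, with genes independent of each other, 53.0% of 2-fold and 90.4% of 4-fold ones were recovered.

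Under corn oil, tamoxifen went with higher stromal and immune markers and lower epithelial ones. The fibroblast and matrix list had 27 of 30 members positive, with a median of 0.77 and slide medians of 0.17, 1.57 and 0.49 (adjusted p = 2.75e-05, and adjusted p = 0.671 with an estimated correlation). Adjusted over the list alone 3 members passed, among them the matrix proteins Fmod (1.76 ± 0.39) and Ogn (2.38 ± 0.66). The T and NK cell list was positive in 19 of 20 members, with a median of 0.85 and slide medians of 0.95, 1.89 and 0.30 (adjusted p = 0.00242, and adjusted p = 0.671 with an estimated correlation), and 3 passed adjusted over the list alone. Interferon response genes were positive in 34 of 40, with a median of 0.72 and slide medians of 0.73, -0.26 and 1.28 (adjusted p = 0.000621, and adjusted p = 0.671 with an estimated correlation). Macrophage and dendritic cell genes were positive in 21 of 24 (median 0.53, adjusted p = 0.00327, and adjusted p = 0.671 with an estimated correlation), with 2 past the list alone. Mast cell genes were positive in 12 of 13 (median 1.00, adjusted p = 0.0162, and adjusted p = 0.671 with an estimated correlation). B and plasma cell genes were positive in 6 of 6 (median 0.72, adjusted p = 0.0287, and adjusted p = 0.671 with an estimated correlation), and the B cell receptor gene Cd22 (2.15 ± 0.42) was 1 of 2 past the list alone. Luminal epithelial genes were lower (18 of 24 negative, median -0.39, adjusted p = 0.00485, and adjusted p = 0.671 with an estimated correlation). Of these, the tight junction gene Cldn7 (-1.03 ± 0.24) and the keratin gene Krt8 (-1.08 ± 0.28) passed adjusted over the list alone. Milk genes were negative in 15 of 19 (median -0.46, adjusted p = 0.0287, and adjusted p = 0.671 with an estimated correlation), with Aldoc (-0.88 ± 0.22) past the list alone. Immediate early genes were negative in 18 of 24 (median -0.47, adjusted p = 0.0277, and adjusted p = 0.671 with an estimated correlation). Proliferation genes were negative in 37 of 47, with a median of -0.24 and slide medians of -0.78, -0.10 and 0.19 (adjusted p = 0.0282, and adjusted p = 0.843 with an estimated correlation). The other 16 lists had adjusted p from 0.0945 (cholesterol synthesis) to 0.928 (endothelial). The call for milk genes was lost without corn oil 2 (median -0.60), corn oil 3 (-0.48) and corn oil + tamoxifen 2 (-0.33). The call for proliferation was lost without corn oil 1 (median 0.11), corn oil 3 (-0.14) and corn oil + tamoxifen 2 (0.10). The call for T and NK cell genes was lost without corn oil + tamoxifen 2 (median 0.27). The call for B and plasma cell genes was lost without corn oil 1 (median 0.67), corn oil 3 (0.77) and corn oil + tamoxifen 2 (0.35). The call for macrophage genes was lost without corn oil + tamoxifen 2 (median 0.33). The call for mast cell genes was lost without corn oil 3 (median 0.47) and corn oil + tamoxifen 2 (0.36). The call for interferon genes was lost without corn oil 1 (median 0.56). The call for luminal genes was lost without corn oil + tamoxifen 2 (median -0.34). The call for immediate early genes was lost without corn oil 2 (median -0.09), corn oil 3 (-0.41) and corn oil + tamoxifen 2 (-0.33). Calls stood, with medians moved by over 1.5 times, for proliferation (-0.66 without corn oil 2 and -0.50 without corn oil + tamoxifen 3) and T and NK cell genes (1.48 without corn oil + tamoxifen 3). Others were mast cell genes (1.51 without corn oil + tamoxifen 1) and luminal genes (-0.25 without corn oil 2). Also moved were fibroblast genes (0.41 without corn oil 2) and immediate early genes (-0.77 without corn oil 1).

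No single gene passed limma's threshold under corn oil, and 3254 had an unadjusted p under 0.05. The smallest adjusted p was 0.0718, for Dgkb, at least 5.29-fold higher than in the corn oil group, where no array was well above background, but its log2 change was 0.70 under normexp. The groups did not overlap in 22.1% of the genes, against 10% by chance. Also among the smallest p were higher values for the transcription factor subunit Nfkb1 (1.19 ± 0.19) and Synj1, a lipid phosphatase of vesicle traffic (1.11 ± 0.18). Ldb3, a protein of the muscle Z disc, had 1.91 ± 0.31 and the kinase gene Prkcb 1.44 ± 0.26. On the lower side were Chl1 (-2.12 ± 0.39), Tomm40 of the mitochondrial import pore (-1.12 ± 0.22) and Spin1 (-1.39 ± 0.27), all with adjusted p from 0.0905 to 0.0946. In simulations 21.2% of 2-fold and 69.8% of 4-fold changes were recovered. Without corn oil + tamoxifen 3, 1 gene passed, and weighting the arrays gave 23.

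Under fish oil, tamoxifen went with lower fat, vessel and milk transcripts and higher immune ones. All 16 tested adipocyte genes were negative, with a median of -1.91 and slide medians of -1.71, -2.29 and -2.11 (adjusted p = 1.46e-15, and adjusted p = 0.131 with an estimated correlation), and 10 passed adjusted over the list alone. Examples were the lipogenic regulator Thrsp (-2.29 ± 0.44), the glyceroneogenic enzyme gene Pck1 (-4.43 ± 1.08) and the glycerol channel gene Aqp7. Aqp7 was at least 3.72-fold lower and not well above background on any array of the combined treatment. All 19 endothelial genes were negative, with a median of -0.98 and slide medians of -0.46, -1.06 and -1.22 (adjusted p = 1.08e-12, and adjusted p = 0.157 with an estimated correlation). Ramp2 (-1.21 ± 0.35) and Sox18 (-1.27 ± 0.36) passed adjusted over the list alone. Of the milk list, 18 of 19 were negative, with a median of -0.96 and slide medians of -1.10, -0.34 and -1.41 (adjusted p = 3.53e-11, and adjusted p = 0.0613 with an estimated correlation). By fry the milk list had adjusted p = 0.0358, and 6 members passed the list alone, among them the casein gene Csn1s1 (-2.10 ± 0.58). T and NK cell genes were positive in 19 of 20, with a median of 1.60 and slide medians of 2.20, 2.48 and -0.01 (adjusted p = 6.66e-15, and adjusted p = 0.167 with an estimated correlation). Of these, 10 passed adjusted over the list alone, among them Sh2d1a (2.38 ± 0.48), Ccl5 (2.12 ± 0.51) and the granzyme gene Gzmk (2.10 ± 0.51). Mast cell genes were positive in 12 of 13, with a median of 1.80 and slide medians of 2.42, 0.97 and 2.33 (adjusted p = 1.88e-09, and adjusted p = 0.167 with an estimated correlation). In that list 7 passed the list alone, among them Cpa3 (2.35 ± 0.53), the chymase gene Cma1 (1.75 ± 0.46) and the histamine-forming enzyme gene Hdc (2.10 ± 0.56).

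Other list shifts under fish oil included B and plasma cell genes (6 of 6 positive, median 1.07, adjusted p = 8.06e-05, and adjusted p = 0.0919 with an estimated correlation), with adjusted p = 0.0358 by fry and Fcrla (1.11 ± 0.28) past the list alone. Macrophage and dendritic cell genes were positive in 23 of 24 (median 0.43, slide medians of 1.17, 0.80 and -0.49, adjusted p = 2.12e-05, and adjusted p = 0.379 with an estimated correlation). Fibroblast and matrix genes were negative in 28 of 30 (median -0.43, adjusted p = 7.31e-06, and adjusted p = 0.379 with an estimated correlation). Cholesterol synthesis was positive in 17 of 22 (median 0.36, adjusted p = 0.00685, and adjusted p = 0.499 with an estimated correlation), antigen presentation in 16 of 20 (median 0.27, adjusted p = 0.0132, and adjusted p = 0.383 with an estimated correlation) and cytokines in 13 of 20 (median 0.29, adjusted p = 0.0236, and adjusted p = 0.345 with an estimated correlation). Erythroid genes were negative in 5 of 5 (median -0.97, adjusted p = 0.0236, and adjusted p = 0.157 with an estimated correlation). Invasion and metastasis genes were negative in 22 of 33 (median -0.20, adjusted p = 0.0381, and adjusted p = 0.379 with an estimated correlation) and luminal epithelial genes in 15 of 24 (median -0.20, adjusted p = 0.0381, and adjusted p = 0.363 with an estimated correlation). PPAR targets and fatty acid oxidation genes were negative in 21 of 29 (median -0.10, adjusted p = 0.0381, and adjusted p = 0.449 with an estimated correlation). The lipase inhibitor gene Angptl4 (-2.19 ± 0.46) was among those past the list alone. Proliferation was positive in 40 of 47 (median 0.32, adjusted p = 0.0415, and adjusted p = 0.728 with an estimated correlation). With slide as a block the invasion list had adjusted p = 0.0685 and the proliferation list adjusted p = 0.0647. The other 10 lists had adjusted p from 0.0697 (myoepithelial and basal) to 0.948 (interferon response, 16 of 40 positive). The call for proliferation was lost without corn oil 3 (median 0.32), corn oil + tamoxifen 1 (0.32), fish oil 1 (0.10), fish oil 3 (0.17), fish oil + tamoxifen 2 (0.19) and fish oil + tamoxifen 3 (0.26). The call for invasion genes was lost without fish oil 1 (median -0.26), fish oil 2 (-0.10), fish oil 3 (-0.20) and fish oil + tamoxifen 3 (-0.13). The call for antigen presentation was lost without fish oil 1 (median 0.17), fish oil + tamoxifen 1 (0.21) and fish oil + tamoxifen 2 (0.17). The call for cytokine genes was lost without fish oil 2 (median 0.28), fish oil + tamoxifen 1 (0.12) and fish oil + tamoxifen 2 (0.29). The call for cholesterol genes was lost without fish oil 1 (median 0.14), fish oil 3 (0.21) and fish oil + tamoxifen 2 (0.18). The call for PPAR targets was lost without fish oil 2 (median 0.00), fish oil 3 (-0.06), fish oil + tamoxifen 1 (-0.03) and fish oil + tamoxifen 2 (-0.08). The call for luminal genes was lost without corn oil 3 (median -0.20), fish oil 1 (-0.25), fish oil 3 (-0.02) and fish oil + tamoxifen 1 (-0.01). The call for erythroid genes was lost without fish oil 3 (median -0.70) and fish oil + tamoxifen 2 (-0.72). Medians moved by over 1.5 times without loss of the call for proliferation (0.56 without fish oil 2 and 0.52 without fish oil + tamoxifen 1) and invasion genes (-0.35 without fish oil + tamoxifen 2). Others were macrophage genes (0.24 without fish oil + tamoxifen 1, 0.25 without fish oil + tamoxifen 2 and 0.82 without fish oil + tamoxifen 3) and antigen presentation (0.42 without fish oil 2). Also moved were cholesterol genes (0.63 without fish oil 2) and PPAR targets (-0.27 without fish oil 1 and -0.20 without fish oil + tamoxifen 3). Further ones were luminal genes (-0.11 without fish oil 2) and fibroblast genes (-0.22 without fish oil + tamoxifen 3). Further ones were erythroid genes (-0.35 without fish oil 2).

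One gene passed limma's threshold for tamoxifen under fish oil, and 1140 had an unadjusted p under 0.05. Cesl1 was at least 1.96-fold lower (adjusted p = 0.0215), a bound because no array of the combined treatment was well above background. Its call was lost in 7 of the 12 fits with an array left out, and 6 genes passed without fish oil 2. Fitting these 2 groups alone gave 11 genes, weighting the arrays 51, the slide block 2, and normexp background correction 0. The groups did not overlap in 13.6% of the genes, against 10% by chance, and 21.4% of simulated 2-fold and 74.6% of 4-fold changes were recovered. Across genes, the tamoxifen changes under the 2 diets, which share no array, had Pearson's r = 0.308 and Spearman's rho = 0.352, where genes are not independent replicates. Of 411 genes with an unadjusted p under 0.05 under both diets, against 224.1 for independent tests, 350 had the same sign. Both tests use each gene's variance over all 12 arrays, so they are not independent and 224.1 is no measure of chance.

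**Figure D2:**
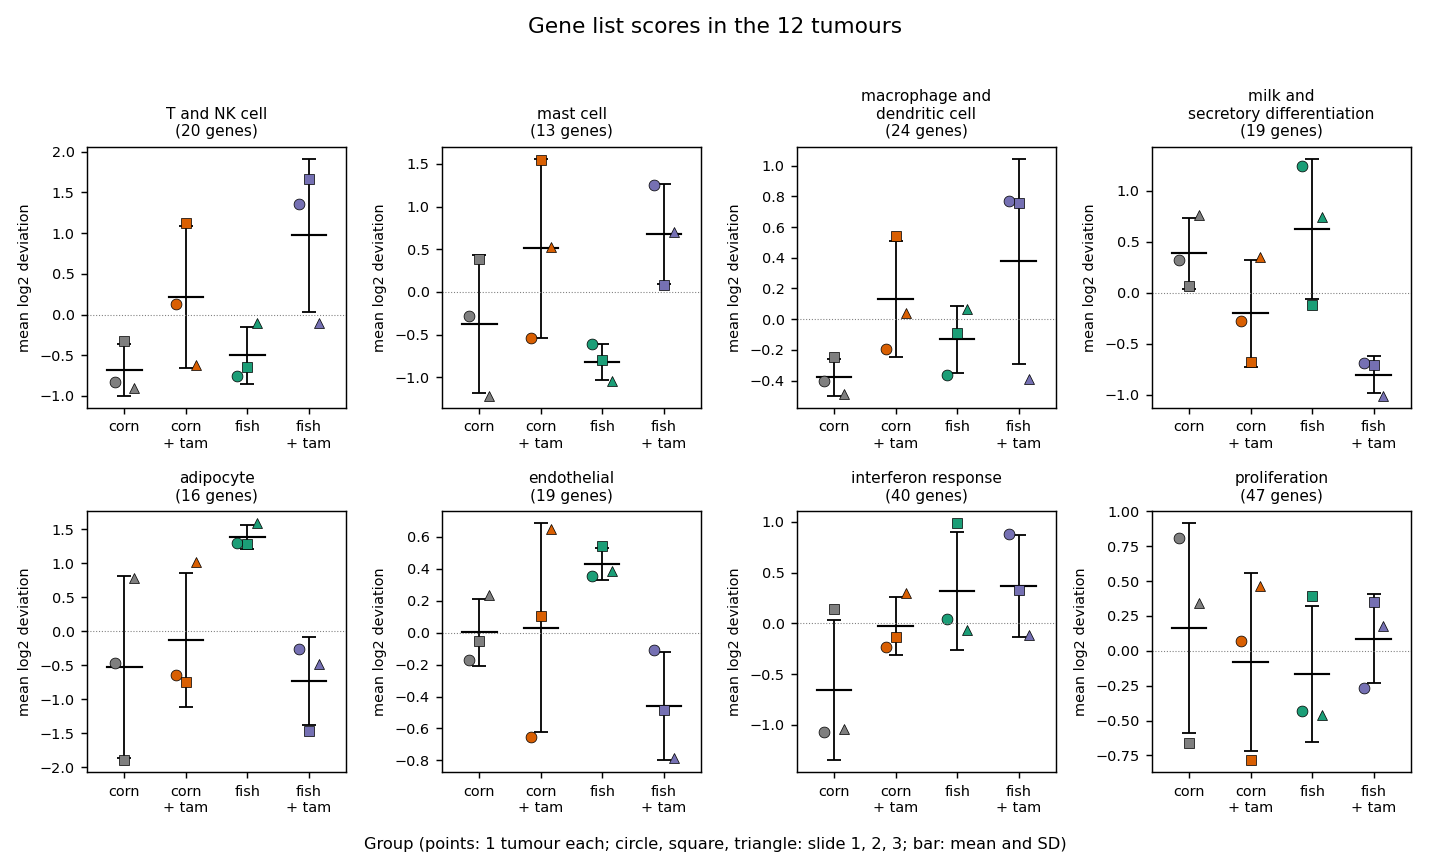
Score of 8 gene lists in the 12 tumours, as the mean over list members of the log2 signal minus the gene's mean over all arrays. Points are single tumours, with the slide given by the symbol, and bars are the group mean and SD (n = 3); the 3 fish oil tumours have the highest adipocyte scores (1.29, 1.28 and 1.59).

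Without tamoxifen, fish oil against corn oil went with higher interferon response, fat cell and stromal transcripts. The interferon response list was positive in 36 of 40 members, with a median of 0.81 and slide medians of 0.99, 0.98 and 0.89 (adjusted p = 9.23e-21, and adjusted p = 0.494 with an estimated correlation). Of its members 10 passed adjusted over the list alone, among them Ifi44l (1.25 ± 0.29), Rigi, a sensor of viral RNA (1.66 ± 0.40), and Ifi44 (1.57 ± 0.42). Adipocyte genes were positive in 15 of 16, with a median of 1.71 and slide medians of 1.70, 3.02 and 0.86 (adjusted p = 6.57e-15, and adjusted p = 0.457 with an estimated correlation). Of these, 12 passed adjusted over the list alone, among them the fatty acid-binding protein gene Fabp4 (3.23 ± 1.00), Pck1 (3.50 ± 1.08) and Thrsp (1.60 ± 0.45). Without corn oil 2, Fabp4 had 2.12 and Pck1 2.22. The fat cell regulator gene Pparg had 1.02 ± 0.31 and was negative under normexp. The adipocyte median was 1.17 without corn oil 2, whose adipocyte score was the lowest of the 12. Fibroblast and matrix genes were positive in 29 of 30, with a median of 0.63 and slide medians of 0.51, 1.45 and -0.04 (adjusted p = 5.97e-13, and adjusted p = 0.494 with an estimated correlation). Endothelial genes were positive in 16 of 19 (median 0.50, adjusted p = 0.000274, and adjusted p = 0.494 with an estimated correlation) and antigen presentation genes in 17 of 20 (median 0.23, adjusted p = 0.000335, and adjusted p = 0.494 with an estimated correlation). The class II gene RT1-Ba was not well above background on any array of the corn oil group and at least 8.81-fold higher with fish oil (adjusted p = 0.709), though its log2 change was 1.36 under normexp. It lies in a region that varies between outbred rats. Immediate early genes were lower (20 of 24 negative, median -0.44, adjusted p = 0.00125, and adjusted p = 0.494 with an estimated correlation). Proliferation was negative in 44 of 47 (median -0.33, adjusted p = 0.00353, and adjusted p = 0.681 with an estimated correlation), with slide medians of -1.46, 1.09 and -0.82. Macrophage genes were higher (18 of 24, median 0.23, adjusted p = 0.00851, and adjusted p = 0.681 with an estimated correlation). The other 18 lists had adjusted p from 0.0604 (milk) to 0.734. The call for proliferation was lost without corn oil 1 (median 0.01), corn oil 3 (-0.27) and fish oil 3 (-0.24). The call for macrophage genes was lost without corn oil 1 (median 0.19) and fish oil 3 (0.14). The call for immediate early genes was lost without corn oil 2 (median -0.12). Still called, with moved medians, were proliferation (-0.79 without corn oil 2, -0.18 without fish oil 1 and -0.62 without fish oil 2) and macrophage genes (0.37 without fish oil 1). Others were antigen presentation (0.38 without corn oil 2 and 0.45 without fish oil 1) and interferon genes (1.21 without corn oil 2 and 0.52 without fish oil 2). Also moved were fibroblast genes (0.96 without corn oil 3) and endothelial genes (0.31 without corn oil 2). Further ones were immediate early genes (-0.76 without corn oil 1).

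No gene passed limma's threshold for fish oil without tamoxifen, and 892 had an unadjusted p under 0.05, near the share expected with no change. The smallest adjusted p was 0.0841, for Cesl1 (at least 1.66-fold higher). The related esterase gene Ces1e (at least 1.74-fold), the serotonin receptor gene Htr2b (at least 1.86-fold) and Cyp4b1 (at least 1.12-fold) came next. All 4 were not well above background on any array of the corn oil group and had the opposite sign under normexp. Under normexp without background-outlier spots they stayed positive, at 1.01 for Cesl1, 1.112 for Ces1e, 0.825 for Htr2b and 0.568 for Cyp4b1. The myelin protein gene Pmp22 had 0.96 ± 0.22. On the lower side were Camk2n1 (-1.16 ± 0.26), Serpinb10 (-2.88 ± 0.70), G2e3 (at least 1.30-fold), Treml1 (-1.69 ± 0.44) and the water channel gene Aqp3 (-1.31 ± 0.35), with adjusted p = 0.709. With slide as a block 2 genes passed, as without corn oil + tamoxifen 2, and 1 gene passed without corn oil 3 or fish oil 3. The groups did not overlap in 9.03% of the genes, against 10% by chance, and 16.4% of simulated 2-fold and 72.8% of 4-fold changes were recovered.

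With tamoxifen, fish oil against corn oil went with higher T cell and antigen presentation values and lower stromal ones. T and NK cell genes were positive in 20 of 20, with a median of 0.74 and slide medians of 1.21, 0.34 and 0.58 (adjusted p = 5e-06, and adjusted p = 0.674 with an estimated correlation), and Cd8a had 1.86 ± 0.78. Antigen presentation genes were positive in 19 of 20, with a median of 0.45 (adjusted p = 2.06e-05, and adjusted p = 0.649 with an estimated correlation). Interferon response genes were positive in 32 of 40, with a median of 0.40 and slide medians of 1.07, 0.41 and -0.43 (adjusted p = 7.41e-05, and adjusted p = 0.704 with an estimated correlation). The immunoproteasome gene Psmb8 had 1.09 ± 0.36. Cholesterol synthesis genes were positive in 19 of 22, with a median of 0.31 (adjusted p = 9.31e-05, and adjusted p = 0.674 with an estimated correlation). Fibroblast and matrix genes were negative in 27 of 30, with a median of -0.52 and slide medians of 0.34, -0.65 and -1.24 (adjusted p = 2.06e-05, and adjusted p = 0.674 with an estimated correlation), among them the surface protein gene Thy1 (-0.74 ± 0.21). Endothelial genes were negative in 18 of 19 (median -0.50, adjusted p = 0.000175, and adjusted p = 0.674 with an estimated correlation) and adipocyte genes in 14 of 16 (median -0.70, adjusted p = 0.0402, and adjusted p = 0.704 with an estimated correlation). Erythroid genes were negative in 5 of 5 (median -0.87, adjusted p = 0.0402, and adjusted p = 0.649 with an estimated correlation). Proliferation (32 of 47 positive, median 0.20, adjusted p = 0.0148, and adjusted p = 0.737 with an estimated correlation) and macrophage genes (19 of 24 positive, median 0.24, adjusted p = 0.0348, and adjusted p = 0.704 with an estimated correlation) were higher. No member of these 10 lists passed adjusted over its list alone. The other 16 lists had adjusted p from 0.116 (apoptosis) to 0.697. The call for proliferation was lost without corn oil + tamoxifen 2 (median -0.21) and fish oil + tamoxifen 2 (0.06). The call for T and NK cell genes was lost without corn oil + tamoxifen 3 (median 0.37). The call for macrophage genes was lost without corn oil + tamoxifen 1 (median 0.08), corn oil + tamoxifen 3 (0.20), fish oil + tamoxifen 1 (0.04) and fish oil + tamoxifen 2 (0.06). The call for interferon genes was lost without fish oil + tamoxifen 1 (median 0.10). The call for cholesterol genes was lost without corn oil + tamoxifen 2 (median 0.15). The call for adipocyte genes was lost without corn oil + tamoxifen 2 (median -0.99), corn oil + tamoxifen 3 (0.04), fish oil 1 (-0.70), fish oil 2 (-0.70), fish oil + tamoxifen 2 (-0.17) and fish oil + tamoxifen 3 (-0.70). The call for fibroblast genes was lost without corn oil + tamoxifen 2 (median -0.40) and fish oil + tamoxifen 3 (-0.30). The call for endothelial genes was lost without corn oil + tamoxifen 2 (median -0.49), corn oil + tamoxifen 3 (-0.24) and fish oil + tamoxifen 3 (-0.43). The call for erythroid genes was lost without corn oil 2 (median -0.87), corn oil + tamoxifen 2 (-0.50), fish oil + tamoxifen 2 (-0.77) and fish oil + tamoxifen 3 (-0.69). With the call kept, medians moved for proliferation (0.43 without corn oil + tamoxifen 3, 0.39 without fish oil + tamoxifen 1 and 0.13 without fish oil + tamoxifen 3) and T and NK cell genes (1.29 without corn oil + tamoxifen 2, 0.42 without fish oil + tamoxifen 2 and 1.23 without fish oil + tamoxifen 3). Others were macrophage genes (0.46 without corn oil + tamoxifen 2 and 0.50 without fish oil + tamoxifen 3) and antigen presentation (0.27 without fish oil + tamoxifen 1 and 0.70 without fish oil + tamoxifen 3). Also moved were interferon genes (0.24 without corn oil + tamoxifen 1) and cholesterol genes (0.59 without corn oil + tamoxifen 3 and 0.48 without fish oil + tamoxifen 1). Further ones were endothelial genes (-0.84 without corn oil + tamoxifen 1).

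No gene passed limma's threshold for fish oil with tamoxifen under any of the alternatives. An unadjusted p under 0.05 was found for 816, near the share expected with no change. The smallest p-values, with adjusted p from 0.895 to 0.918, included Ghrh (at least 2.24-fold higher), Snx10 (1.28 ± 0.29) and Fut1 (0.82 ± 0.20). The chaperonin gene Cct6a had 0.97 ± 0.25 and Copz1 0.79 ± 0.21. On the lower side were Lrrn1 (-1.94 ± 0.37), Ldb3 (-1.61 ± 0.31), the endothelial gene Mmrn2 (-1.67 ± 0.36), the protease gene Adamts7 (-1.15 ± 0.25) and Pcsk6 (-1.45 ± 0.33). The groups did not overlap in 10.6% of the genes, against 10% by chance, and 16.6% of simulated 2-fold and 76.0% of 4-fold changes were recovered. Across genes, the fish oil changes with and without tamoxifen had Pearson's r = -0.13 and Spearman's rho = -0.08. Of 88 genes with an unadjusted p under 0.05 in both, against 44 for independent tests, 26 had the same sign. These tests share the variance of each gene too, so 44 is no measure of chance.

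Tumours with fish oil and tamoxifen together, against corn oil alone, had higher immune and interferon transcripts and lower ones of milk and red blood cells. Interferon response genes were positive in 39 of 40, with a median of 0.87 and slide medians of 1.58, 0.22 and 0.82 (adjusted p = 1.25e-13, and adjusted p = 0.314 with an estimated correlation). Of these, 11 passed adjusted over the list alone, 10 of them higher, among them the chemokine gene Cxcl10 (2.19 ± 0.44). T and NK cell genes were positive in 20 of 20, with a median of 1.56 and slide medians of 2.04, 1.99 and 0.62 (adjusted p = 1.4e-13, and adjusted p = 0.253 with an estimated correlation). In this list 12 passed the list alone, the NK cell receptor gene Klrd1 (3.02 ± 0.63) and Gzmk (2.44 ± 0.51) among them. Macrophage genes were positive in 22 of 24 (median 0.71, slide medians of 1.13, 1.06 and -0.03, adjusted p = 3.76e-08, and adjusted p = 0.314 with an estimated correlation), with 8 past the list alone. Antigen presentation genes were positive in 19 of 20 (median 0.71, adjusted p = 5.5e-07, and adjusted p = 0.227 with an estimated correlation), with the class II genes Cd74 (1.30 ± 0.33) and RT1-Da (1.38 ± 0.36) past the list alone. B and plasma cell genes were positive in 5 of 6 (median 1.16, adjusted p = 0.000236, and adjusted p = 0.227 with an estimated correlation), with adjusted p = 0.0257 by fry and 4 past the list alone, Cd22 at 2.20 ± 0.42 among them. Mast cell genes were positive in 13 of 13 (median 0.95, adjusted p = 0.00014, and adjusted p = 0.335 with an estimated correlation) and cytokines in 15 of 20 (median 0.44, adjusted p = 0.00532, and adjusted p = 0.253 with an estimated correlation). Milk genes were negative in 17 of 19 (median -0.75, adjusted p = 0.00014, and adjusted p = 0.227 with an estimated correlation), with Csn1s1 (-2.19 ± 0.58) and Olah (-1.68 ± 0.47) past the list alone. Erythroid genes were negative in 4 of 5 (median -1.88, adjusted p = 0.0113, and adjusted p = 0.227 with an estimated correlation), with adjusted p = 0.028 by fry. The globin gene Hbb-b1 (-1.88 ± 0.49), Ahsp (-1.97 ± 0.52) and the heme enzyme gene Alas2 (-2.52 ± 0.71) passed the list alone. Immediate early genes were lower (20 of 24 negative, median -0.64, adjusted p = 0.000305, and adjusted p = 0.33 with an estimated correlation), as were luminal genes (21 of 24 negative, median -0.30, adjusted p = 0.00532, and adjusted p = 0.253 with an estimated correlation). Endothelial genes were negative in 14 of 19 (median -0.50, adjusted p = 0.00532, and adjusted p = 0.557 with an estimated correlation), with the transcription factor gene Erg (-1.95 ± 0.51) past the list alone. The other 14 lists had adjusted p from 0.0598 (fibroblast and matrix) to 0.96. The call for cytokine genes was lost without corn oil 1 (median 0.42). The call for luminal genes was lost without corn oil 2 (median -0.30) and fish oil + tamoxifen 1 (-0.10). The call for endothelial genes was lost without fish oil + tamoxifen 3 (median -0.39). The call for immediate early genes was lost without corn oil 2 (median -0.23). Medians moved by over 1.5 times, with the call kept, for milk genes (-0.48 without fish oil + tamoxifen 1) and macrophage genes (1.09 without fish oil + tamoxifen 3). Others were mast cell genes (0.61 without corn oil 3 and 0.56 without fish oil + tamoxifen 1) and antigen presentation (0.46 without corn oil 3). Also moved were cytokine genes (0.25 without fish oil + tamoxifen 1 and 0.73 without fish oil + tamoxifen 3) and immediate early genes (-0.96 without corn oil 1, -0.38 without corn oil 3 and -0.42 without fish oil + tamoxifen 3).

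No gene passed limma's threshold for the combination, and 1958 had an unadjusted p under 0.05. The smallest adjusted p was 0.0757, for the NK cell receptor gene Klri2 (at least 2.38-fold higher) and Dgkb (at least 4.13-fold). Gpr141 (at least 1.85-fold), Rgs18, a regulator of G-protein signalling in blood cells (1.82 ± 0.32), and Tasl of endosomal toll-like receptor signalling (1.42 ± 0.26) followed. On the lower side were Npw (-2.15 ± 0.33), Stox2 (at least 1.82-fold), the neuronal filament gene Prph (-1.74 ± 0.33), Kctd17 (-1.04 ± 0.20) and Qtrt1 (-0.97 ± 0.19), with adjusted p from 0.0779 to 0.112. Without corn oil 2, 23 genes passed, 8 without fish oil + tamoxifen 3 and 1 without corn oil 1, and weighting the arrays gave 37. The groups did not overlap in 18.5% of the genes, against 10% by chance, and 21.2% of simulated 2-fold and 74.4% of 4-fold changes were recovered.

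Fat and stromal genes had the lowest values in the interaction, the test of whether the tamoxifen change differed between the diets. The adipocyte list was negative in 15 of 16 members, with a median of -2.65 and slide medians of -1.29, -3.67 and -2.52 (adjusted p = 4.17e-11, and adjusted p = 0.385 with an estimated correlation). In it 6 members passed adjusted over the list alone, Thrsp (-2.91 ± 0.63) and the glucose transporter gene Slc2a4 (-2.34 ± 0.67, positive under normexp) among them. The fibroblast and matrix list was negative in 30 of 30, with a median of -1.10 and slide medians of -0.16, -2.07 and -1.12 (adjusted p = 2.39e-14, and adjusted p = 0.385 with an estimated correlation), with 4 past the list alone. The endothelial list was negative in 18 of 19, with a median of -0.92 and slide medians of 0.14, -1.17 and -1.56 (adjusted p = 4.65e-07, and adjusted p = 0.565 with an estimated correlation). Proliferation was positive in 45 of 47 (median 0.55, adjusted p = 2e-04, and adjusted p = 0.904 with an estimated correlation) and cholesterol synthesis in 19 of 22 (median 0.68, adjusted p = 0.000218, and adjusted p = 0.904 with an estimated correlation). Interferon response was negative in 32 of 40 (median -0.61, adjusted p = 0.000256, and adjusted p = 0.904 with an estimated correlation) and milk in 16 of 19 (median -0.50, adjusted p = 0.0268, and adjusted p = 0.687 with an estimated correlation). Among positive lists was T and NK cell (18 of 20, median 0.49, adjusted p = 0.0268, and adjusted p = 0.904 with an estimated correlation). The other 18 lists had adjusted p from 0.0503 (apoptosis) to 0.986. The call for milk genes was lost without corn oil 1 (median -0.38), corn oil + tamoxifen 2 (-0.65), corn oil + tamoxifen 3 (-0.52), fish oil 1 (-0.36), fish oil 3 (-0.39), fish oil + tamoxifen 1 (-0.54) and fish oil + tamoxifen 3 (-0.50). The call for proliferation was lost without corn oil 1 (median 0.18) and corn oil + tamoxifen 2 (0.18). The call for T and NK cell genes was lost without corn oil 2 (median 0.40), corn oil + tamoxifen 1 (0.57), corn oil + tamoxifen 3 (0.01), fish oil 1 (0.36), fish oil 2 (0.46), fish oil + tamoxifen 1 (0.36) and fish oil + tamoxifen 2 (0.11). The call for interferon genes was lost without corn oil 1 (median -0.58), fish oil 2 (-0.29) and fish oil + tamoxifen 3 (-0.43). The call for cholesterol genes was lost without corn oil + tamoxifen 2 (median 0.33). Medians moved by over 1.5 times, with the call kept, for milk genes (-0.99 without fish oil 2) and proliferation (0.99 without corn oil 2, 0.85 without corn oil + tamoxifen 3, 0.34 without fish oil 1 and 0.86 without fish oil 2). Others were T and NK cell genes (1.11 without corn oil + tamoxifen 2 and 1.04 without fish oil + tamoxifen 3) and cholesterol genes (0.38 without fish oil 1). Also moved were endothelial genes (-0.57 without corn oil + tamoxifen 3).

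No gene passed limma's threshold for the interaction, and 1102 had an unadjusted p under 0.05. In simulations 1.80% of 2-fold and 39.8% of 4-fold differences were recovered. The smallest adjusted p was 0.276, for Cesl1, followed on the negative side by Htr2b (at least 3.58-fold), Ces1e, Ldb3 (-2.36 ± 0.44) and the aldehyde oxidase gene Aox1 (-3.85 ± 0.73). Cesl1 and Ces1e were well above background in the fish oil group alone, so no size is given. Both of them and Htr2b were positive under normexp, but not under normexp without background-outlier spots. On the positive side were Lmnb1 of the nuclear lamina (1.90 ± 0.45), the aldehyde-reducing enzyme gene Akr7a3 (2.23 ± 0.53), Trim13 (1.87 ± 0.49) and Mllt11 (1.44 ± 0.38), with adjusted p from 0.608 to 0.643. With slide as a block 1 gene passed, and without corn oil + tamoxifen 2, 2 passed.

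Averaged over tamoxifen and no tamoxifen, fish oil went with higher interferon response values. The list was positive in 39 of 40 members, with a median of 0.66 and slide medians of 1.10, 0.73 and 0.22 (adjusted p = 4.34e-24, and adjusted p = 0.326 with an estimated correlation). Ifi44l (0.94 ± 0.21) alone passed adjusted over the list, and Mx2, an antiviral GTPase, had 2.20 ± 0.62. Antigen presentation genes were positive in 19 of 20 (median 0.46, slide medians of 0.49, 0.43 and 0.40, adjusted p = 1.04e-09, and adjusted p = 0.326 with an estimated correlation). Positive too were T and NK cell genes in 18 of 20 (median 0.49, adjusted p = 8.06e-06, and adjusted p = 0.587 with an estimated correlation) and macrophage genes in 20 of 24 (median 0.27, adjusted p = 0.000206, and adjusted p = 0.629 with an estimated correlation). Adipocyte genes were positive in 15 of 16 (median 0.61, slide medians of 1.00, 1.18 and -0.37, adjusted p = 1.46e-05, and adjusted p = 0.522 with an estimated correlation), but the median was 1.71 without tamoxifen and -0.70 with it (14 of 16 negative). Immediate early genes were lower (19 of 24 negative, median -0.31, adjusted p = 0.00197, and adjusted p = 0.587 with an estimated correlation), as were erythroid genes (4 of 5 negative, median -0.96, adjusted p = 0.0267, and adjusted p = 0.326 with an estimated correlation). The other 19 lists had adjusted p from 0.0665 (skeletal muscle) to 0.994. The call for erythroid genes was lost without corn oil 2 (median -0.79), corn oil + tamoxifen 2 (-0.88) and fish oil + tamoxifen 3 (-0.97). The call for immediate early genes was lost without corn oil 2 (median -0.20). Medians moved by over 1.5 times, with the call kept, for T and NK cell genes (0.22 without corn oil + tamoxifen 3, 0.28 without fish oil + tamoxifen 2 and 0.75 without fish oil + tamoxifen 3) and macrophage genes (0.17 without corn oil + tamoxifen 1, 0.42 without corn oil + tamoxifen 2, 0.17 without fish oil + tamoxifen 1, 0.15 without fish oil + tamoxifen 2 and 0.48 without fish oil + tamoxifen 3). Others were adipocyte genes (0.29 without corn oil 2).

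No gene passed limma's threshold for the average fish oil effect, and the smallest adjusted p was 0.985. An unadjusted p under 0.05 was found for 627, below the share expected with no change. In simulations 56.2% of 2-fold and 90.4% of 4-fold changes were recovered. The transcription factor gene Pou3f3 was at least 13.7-fold lower and was not well above background on any array with fish oil. It was on 2 of the 3 corn oil arrays, where its SD was 4.50 on the log2 scale, and corn oil 2 moved it most among the single arrays. Sbspon (-1.41 ± 0.33), Treml1 (-1.28 ± 0.31), Stox2 (at least 1.28-fold) and Kazald1 (-0.90 ± 0.23) were on the lower side. The NK cell receptor gene Ly49s3 (1.87 ± 0.46) and Gpr160 (0.76 ± 0.19) were on the higher side, as were Akr1e2 and Cesl1, which were well above background in the fish oil group alone. All had adjusted p = 0.985. Pou3f3 alone passed without corn oil 2 (adjusted p = 0.0043, in a range of 0.0043 to 1 over the alternatives), and 1 gene passed without fish oil 3.

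**Figure D3:**
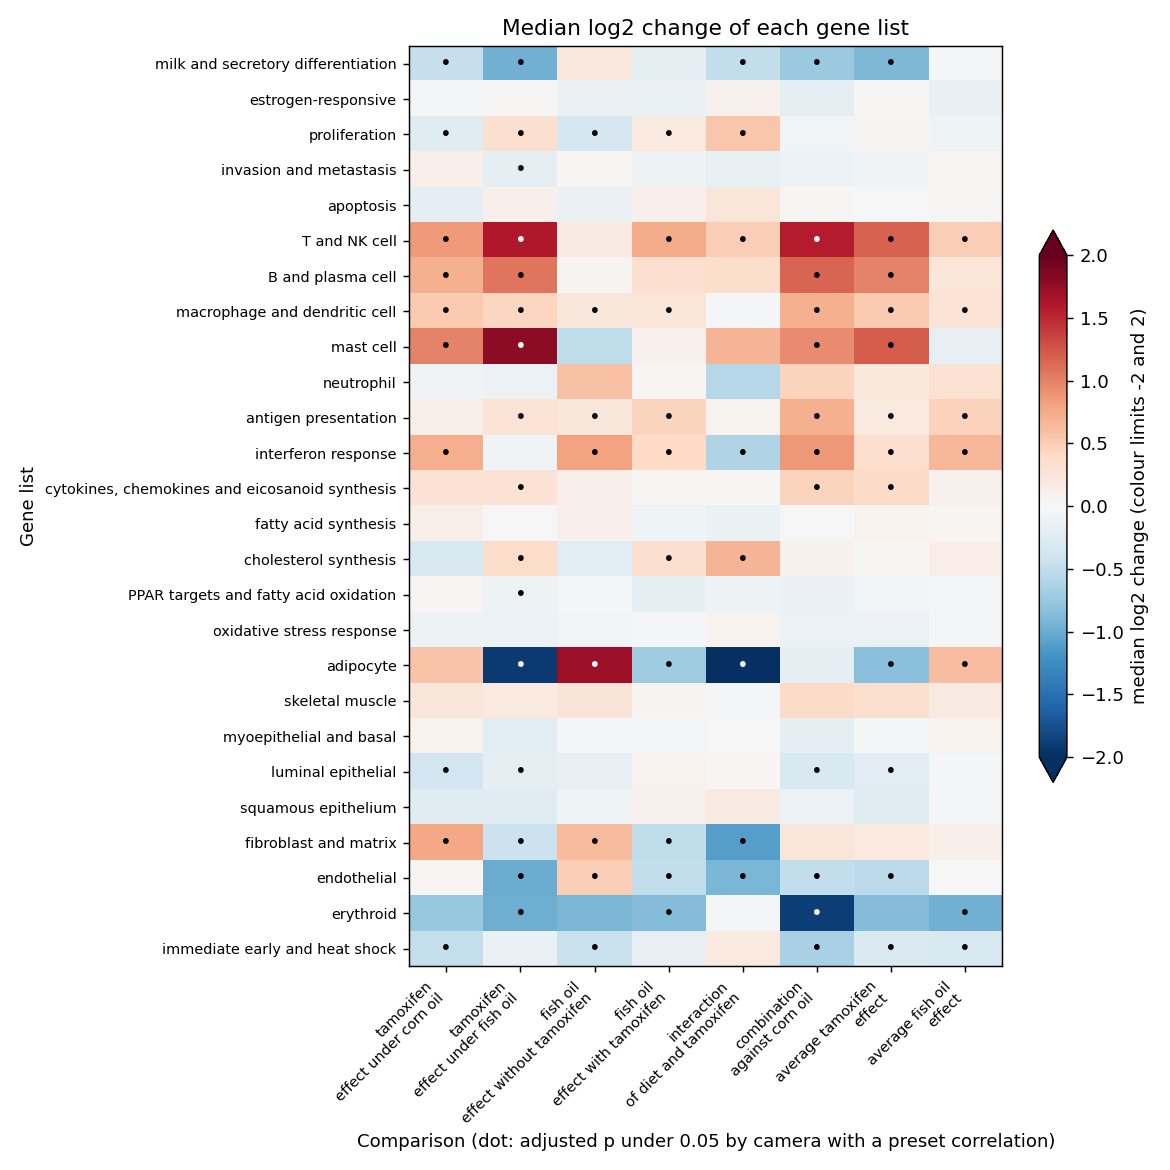
Median log2 change of the 26 gene lists (rows) in the 8 comparisons (columns), as colour. A dot marks adjusted p under 0.05 by camera with the preset correlation; the adipocyte list reaches -1.91 for tamoxifen under fish oil and 1.71 for fish oil without tamoxifen.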

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

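The tests of the share of tumour cells, the test of lymph node tissue and the splits within slides were chosen only after the result was seen.

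Differences between the diets in the tamoxifen change, by the interaction test on gene lists, brought up 8 results. The list medians of the difference were -2.65 for adipocyte, -1.10 for fibroblast and matrix, -0.92 for endothelial, -0.61 for interferon response and -0.50 for milk genes. They were 0.68 for cholesterol synthesis, 0.55 for proliferation and 0.49 for T and NK cell genes. None of the 8 held with an estimated correlation between genes (adjusted p from 0.385 to 0.904), and 57 of 100 splits of the arrays gave as many lists, with up to 15, so chance could not be excluded. No gene passed limma's threshold for the interaction and 1102 had an unadjusted p under 0.05; the highest of the others had 14, and since each of the 100 splits reaches a count of 0, they do not test it against chance.

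Adipocyte genes were higher with fish oil alone and lower with tamoxifen under fish oil. A change in the share of tumour cells would move other non-tumour markers alike. With tamoxifen under fish oil the endothelial score (-0.89 ± 0.32) and the fibroblast score (-0.43 ± 0.37) fell with the adipocyte score (-2.12 ± 0.73). The immune score rose (1.16 ± 0.40), 3.28 ± 0.99 apart from the adipocyte score, which argues against that share as the whole cause there. With fish oil alone the share of tumour cells stays open. The endothelial (0.43 ± 0.32) and fibroblast (0.76 ± 0.37) scores rose with the adipocyte score (1.91 ± 0.73). The immune score did not rise (-0.006 ± 0.397), and the luminal score had -0.107 ± 0.107. The immune score minus the adipocyte score was -1.92 ± 0.99, within 2 standard errors of 0. A single array did not make the pattern, since the weakest list median without 1 array was 0.687 of the full one (without corn oil 2). Fat tissue in the dissected piece and a change of fat cells by the diet, which the design names, cannot be told apart. The 16 adipocyte genes varied together within groups, with a mean correlation of 0.502, but so do genes that are regulated together, and 6 of the 25 other lists had a correlation as high.

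T and NK cell, mast cell and macrophage genes were higher with tamoxifen, averaged over the diets. A lower share of tumour cells would raise vessel and fat markers too. Under fish oil theirs fell (-1.50 ± 0.47) as the immune score rose (1.16 ± 0.40), 2.66 ± 0.69 apart. Under corn oil a lower share of tumour cells stays open: the immune score (0.76 ± 0.40) and the vessel and fat score (0.22 ± 0.47) differed by 0.55 ± 0.69, within 2 standard errors. There the fibroblast score rose by 0.81 ± 0.37 and the luminal score fell by 0.37 ± 0.11. Averaged over the diets, a single array did not make the pattern (lowest ratio 0.721, mast cell genes without corn oil + tamoxifen 2). Under corn oil, leaving out corn oil + tamoxifen 2 took the T and NK cell median from 0.85 to 0.27. The mast cell median went from 1.00 to 0.36, the macrophage median from 0.53 to 0.33, and all these calls were lost. Under that diet the rise thus leaned on that array. Lymph node tissue in the sample stays open: the B and plasma cell score rose by 0.90 ± 0.19, which exceeded 0.5 of the T and NK cell score by 0.30 ± 0.09. An influx of immune cells with tamoxifen may equally lie behind the pattern, and was not tested apart from lymph node tissue.

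Interferon response genes were higher with fish oil, with a score of 0.68 ± 0.31. With the array's 75th percentile as a covariate the score was 0.66 ± 0.34, and with the T and NK and macrophage score as a covariate 0.58 ± 0.34. Both lay within 2 standard errors of 0, so array brightness and immune cell content cannot be told apart from an effect of the diet with 12 arrays. Averaged over tamoxifen and no tamoxifen, a single array did not make the pattern (ratio 0.684, without fish oil 2, where the median was 0.45 against 0.66). With tamoxifen the median went from 0.40 to 0.10 without fish oil + tamoxifen 1. The interferon list shared 0 members with the T and NK and macrophage lists. The interferon and antigen presentation lists share Tap1, Psmb8 and Psmb9.

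The 12 arrays were also split in other ways. For the average tamoxifen effect, 1 of 100 splits gave as many genes, the real one with 78 against 8 for the highest other. That makes chance unlikely for this count but does not exclude it. The count was the highest of 8 comparisons, with no correction for that. Tumours of one slide and diet deviated together, so tamoxifen was also exchanged only within slide and diet. Of these 32 splits, 1 gave as many genes, the real one, with 78 against 3 for the highest other, and with slide as a block 72 against 1. For the lists of the average tamoxifen effect chance could not be excluded: 14 of 100 splits gave 12 or more, up to 16. Lists were not counted in the splits within slide and diet, so these list counts ignore that pairing. For the average fish oil effect the highest other count of genes was 735, and the real count of 0, which each of the 100 splits reaches, is not tested against chance. For its lists chance could not be excluded: 61 of 100 gave as many lists as the 7 called, up to 14. For the comparisons of 3 against 3 arrays the 10 splits are too few. The real and the highest other count of genes were 0 and 0 for tamoxifen under corn oil (as many in 10 of 10), 1 and 0 under fish oil (1 of 10), 0 and 0 for fish oil without tamoxifen (10 of 10), 0 and 62 with tamoxifen (10 of 10), and 0 and 0 for the combination (10 of 10). In the same order, those of lists were 10 and 13 (4 of 10), 16 and 15 (1 of 10), 8 and 9 (3 of 10), 10 and 15 (4 of 10), and 12 and 14 (4 of 10).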

How the results depend on the processing

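The alternative of normexp without background-outlier spots was chosen only after the result was seen. Of 16 calls of 15 named genes, 167 of 355 alternative fits kept the call, 188 lost it and none reversed it. Of 195 values of genes chosen by the naming rule that did not pass, 4428 of 4513 fits left them there, 63 passed and 22 changed sign. Of 83 called lists, 1037 of 1328 fits kept the call, 290 lost it and 1 changed the direction of the test. The list median crossed 0 in 6 of 996 fits without an array. The call was kept without any single array by 39 lists, after quantile normalization by 81, with a block by 81 and by fry by 6. No scaling moved the median of all genes by over 0.1.

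For the average tamoxifen effect (78 genes, 62 higher) normexp gave 0 and no filter on dim probes 3 of 35855 tested. Normexp without background-outlier spots gave 33, and only 59 of the 78 were tested there, with 29 shared. The series matrix values gave 27 of 9245 tested, and 23 of the 34 tested there were shared. The filter on all 12 arrays gave 88 (59 of 59 shared), quantile normalization 94 (74 shared) and median centring 83 (69 shared). The trend and robust options gave 82 (67 shared) and the mean of a gene's probes 71 (67 shared). Array weights gave 528 (318 higher, 210 lower) and leaving out an array 0 to 143. For tamoxifen under fish oil (1 gene) both normexp fits, the trend and robust options and the series matrix gave 0. So did the filter on all 12 arrays, under which Cesl1, the gene called, was not tested. Quantile normalization gave 2, array weights 51, only the 2 groups 11 and leaving out an array 0 to 6. The other comparisons had 0. Under corn oil, the trend and robust options gave 1 and array weights 23 (leaving out an array 0 to 1). For fish oil without tamoxifen, quantile normalization gave 2, median centring 1 and array weights 2 (0 to 2). For the interaction, quantile normalization gave 2 and array weights 2 (0 to 2). For the combination, no filter gave 1 and array weights 37 (0 to 23), and the average fish oil effect had 0 to 1. The cause was not tested.

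An estimated correlation took the called lists to 0 in all 8 comparisons. Fry gave 2 for tamoxifen under fish oil, the combination and the average tamoxifen effect and 0 elsewhere, and fry for either direction gave 1 for tamoxifen under fish oil, 8 for average tamoxifen and 0 elsewhere. Leaving out an array gave 2 to 12 lists for tamoxifen under corn oil (10 called), 10 to 17 under fish oil (16), 6 to 10 for fish oil with tamoxifen (10) and 7 to 11 for average fish oil (7). The cause was not tested.

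Of same-numbered tumours, which share a slide, 10 of 18 pairs over all groups had deviations correlated over 0.1 (-0.274 to 0.428), while 8 of 12 arrays correlated best with their own number. The replicate block, which is also the slide block, gave 2 genes for tamoxifen under fish oil, 2 for fish oil without tamoxifen, 1 for the interaction and 72 for average tamoxifen. Of list calls it changed those of invasion and proliferation for tamoxifen under fish oil and of apoptosis for the interaction.

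Signs turned under normexp for tamoxifen under corn oil in Thy1 (-0.18) and Fcrla (-0.32), for fish oil without tamoxifen in Cesl1 (-0.28), Ces1e (-0.27), Htr2b (-0.30), Cyp4b1 (-0.61), Pparg (-0.083) and Itgam (-0.062), and for the interaction in Cesl1 (0.78), Htr2b (0.18), Ces1e (0.79), Thy1 (0.38) and Slc2a4 (0.073). None turned without background-outlier spots. Pgr (average tamoxifen) was 0.02 with median centring, 0.38 with array weights, 0 in the series matrix and -0.32 to 0.26 leaving out an array. Proliferation turned for fish oil with tamoxifen without corn oil + tamoxifen 2 (adjusted p = 0.746; range leaving out an array adjusted p = 2.28e-07 to adjusted p = 0.746). Dim signal limits the fold bounds, and Esr1 could not be measured.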

Other observations

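The split described here was chosen only after the result was seen. A split that does not follow the groups gave 735 genes in the average fish oil comparison and points to a structure of the samples. One side held corn oil 2, corn oil + tamoxifen 2, fish oil 1, fish oil 3, fish oil + tamoxifen 1 and fish oil + tamoxifen 2. It follows slide in part: 3 of its 6 arrays are from slide 2, and 4 of the 6 pairs of one diet and slide lie on one side. Refitted with limma and tamoxifen in the model, 831 genes differed, 248 higher and 583 lower on that side. With slide also in the model no gene passed, and 3413 had an unadjusted p under 0.05. Without slide, proliferation genes were lower there (45 of 47, median -0.82) and T and NK cell genes higher (20 of 20, median 0.88). The split was taken for its many calls, so these values are no test of it.

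Gene levels separated the arrays only in part: the first principal component held 22.5% of the variance and the second 20%. Corn oil 2 lay at 64.3 on the first, the highest of the 12, and corn oil 3 at -63.3 on the second, the lowest.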
